A study of Homo sapiens with 24 samples.

How the data were processed

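The study profiled CD8+ T cells from the blood of 8 patients before treatment with an antibody against PD-1, an inhibitory receptor on T cells, and again 12 weeks after treatment began. Per the labels' protocols, frozen peripheral blood mononuclear cells were thawed, stained and sorted for CD45, CD3 and CD8, and the sorted cells were captured in droplets so that each transcript carried a cell barcode and a unique molecular identifier (UMI). The 16 gene expression libraries were grouped from the labels into 8 baseline and 8 post-treatment libraries. Patients are called A to H here. The labels name a 3′ v2 library chemistry for the 4 patients A to D and a 5′ chemistry for the 4 patients E to H, so chemistry is a technical batch of patients and constant within a patient. The labels' protocol text describes the 3′ v2 kit alone. Another 8 libraries hold T-cell receptor sequences and were not analysed here. The series description states that 4 patients responded and 4 did not, without tying response to a sample in the labels, so response was not used here, and whether it follows the split by chemistry was not tested.

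The deposited files hold raw UMI counts per gene and cell barcode, 1 matrix per library, as whole numbers with no normalization by the authors. The submitters' processing notes name Cell Ranger 3.1.0 and GRCh38. The annotation release is not given in the sources used here. Every matrix lists 33538 genes with Ensembl identifiers and symbols, 48 of them with a symbol that occurs more than once, which were kept apart by identifier. The labels' protocols state that 2000 to 3000 cells were aimed for in each library. The deposited matrices held 769 to 2830 barcodes per library, 28764 in all, and 2040059 to 13557043 UMIs per library.

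Everything from there on was computed from the counts. Barcodes with under 300 detected genes (564) or over 10% mitochondrial UMIs (4931) were left out, some for both reasons, which left 23801 cells. The filter took between 3.7% and 51.7% of a library's barcodes. Doublets were called per library with Scrublet, as implemented in scanpy 1.11.5, at an expected 0.8% per 1000 cells, and 245 cells (1.03%) were removed. Counts were log-normalized, the 2000 most variable genes were taken without T-cell receptor, immunoglobulin, ribosomal, mitochondrial and sex-linked genes and without NKG7, values were scaled within each chemistry, and 20 principal components were computed. Each cell's 5 nearest neighbours were taken from every patient alike, so that no patient set the graph, and cells were clustered once over all libraries with the Leiden method at resolution 1 (leidenalg 0.10.2). A cluster was named after a cell type only where at least 3 of its 10 leading genes by fold were markers fixed in advance for that type, and more than for any other type. Names end in "-like" because they rest on markers alone. A cluster of 277 monocyte-like cells was removed, and the other 23279 cells are called CD8 cells below. At a higher resolution a B-like cluster of 578 cells was set apart, with IGKC, CD79A, HLA-DRA, HLA-DQA1 and CD74 among its leading genes. The clustering used here had no B-like cluster, so such cells were not removed. Their effect on HLA class II genes and on the classes was not tested.

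Raw counts were summed per library, and per library and class, and these sums were tested, since cells of a patient are not replicates. The main test was edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3) with TMM normalization, filterByExpr, robust dispersion, the patient as a block and a two-sided Benjamini-Hochberg adjusted p under 0.05. The pairing comes from the labels, which give both libraries of a patient the same number. Deviations of the log2 values from the group means correlated between a patient's 2 libraries with r from 0.56 to 0.86 across genes, and from 0.00986 to 0.652 after the chemistry's mean was taken out as well. Then 6 of 8 baseline libraries correlated best with the same patient's own post-treatment library. T-cell receptor and immunoglobulin variable, diversity and joining segments (609) and 91 sex-linked genes were left out of all tests. Within classes, a patient entered with at least 20 cells of the class in both libraries, and a class was tested with at least 5 such patients. Shares of cells, NKG7 levels and means over gene lists were compared with exact two-sided sign-flip permutation tests over patients. With 8 patients the smallest p is 0.00781, with 4 patients 0.125, and over the 8 classes a single class cannot reach an adjusted p under 0.0625. A difference between the chemistries was tested by an exact permutation of the 4 and 4 patients, with a smallest p of 0.0286, and across genes by an interaction term in edgeR. For levels on a log2 scale, 10 was added to the CPM (UMIs scaled to a common total).

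For a question across cells, each cell was thinned at random to 1000 UMIs, shallower cells were left out, and counts were summed over cells with and without an NKG7 UMI, so that depth did not differ between the cells. This left out 323 baseline and 94 post-treatment CD8 cells. Shares of cells with an NKG7 UMI are given both as measured and after this thinning.

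Gene lists were fixed before the data were examined, from general knowledge of T cells: cytotoxic effector, naive and central memory, GZMK effector memory, checkpoint and exhaustion, activation and HLA class II, proliferation, type I interferon response, interferon gamma induced, immediate early, heat shock, cytokines and chemokines, TCR signalling, oxidative phosphorylation, glycolysis, mitochondrially encoded, actin cytoskeleton and migration, lytic granule exocytosis, NK receptors, MAIT, and, as signs of other cells or of RNA quality, gamma delta T, regulatory and CD4 T, B cell, monocyte and dendritic, platelet, erythroid and nuclear RNA. Lists with at least 3 tested genes (23) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. The genes named below follow a rule set in advance. NKG7 and PDCD1 are always named. In a comparison or class where no gene passed, the 10 genes with the smallest unadjusted p are named as not passing. Of each list up to 4 members with the smallest p may be named. Across cells, the 12 largest rises and 12 largest falls past the threshold and in the same direction in all 8 patients are named. Some genes that the rule takes are not reported here. Genes outside this rule are marked as chosen after their values were seen.

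The tests were tried on simulated data with 50 genes changed at each of 4 sizes, drawn from the real means and library sizes. Changed genes were taken only from those above the median level. Each change had the same size in all patients concerned, and random variation was independent between genes. The recovered shares therefore do not cover weaker genes or changes that vary between patients. For all CD8 cells (10768 genes), edgeR recovered 86% of genes changed 1.5-fold, 96% at 2-fold and 100% at 3-fold and 4-fold, and DESeq2 90% at 1.5-fold and 100% above. Unchanged genes made up 15 of the 206 genes called by edgeR and 23 of the 218 called by DESeq2. Within the memory-like class (6075 genes), edgeR recovered 70%, 96%, 100% and 100%. For cells with against without NKG7 (4264 genes), the shares were 26%, 94%, 98% and 98%, and for the interaction with chemistry (10881 genes) 6%, 58%, 100% and 96%. Unchanged were 13 of 196 genes called within the class, 14 of 172 across cells and 8 of 138 in the interaction, so that false calls exceeded 5% of the calls each time. Among simulated lists, the shifted one was called and 0 of 20 unchanged ones were. Since the simulated genes varied independently, this does not show how often camera calls unchanged lists of correlated genes.

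Alternatives covered the normalization (RLE size factors), the tool (DESeq2 1.42.0), the gene filter, the patient block, chemistry as a covariate, each chemistry alone, each patient left out in turn, the cell filters, doublets, depth (every library thinned to 1735869 UMIs), receptor segments, the clustering resolution and neighbour balance, and cell make-up. For the last, cells were drawn so that both libraries of a patient held the same number of cells of each class (17532 cells). Coordinates are those of RefSeq genes in GRCh38.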

Results

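NKG7 encodes a small membrane protein of the cytotoxic granules of natural killer cells and CD8+ T cells. Single-cell RNA was profiled from sorted blood CD8+ T cells of 8 patients at baseline and 12 weeks after treatment with an antibody against PD-1 began, which gave 16 libraries, 8 in each group. The questions were whether NKG7 and other genes differed between the time points and which CD8 cells carried NKG7. The libraries held 2040059 to 13557043 unique molecular identifiers (UMIs) as deposited, and after filtering 557 to 2310 CD8 cells each, 23279 in all, with median depths of 2368 to 6045 UMIs per cell. The 4 patients A to D had 3′ v2 libraries, with a median over libraries of 3358 UMIs per cell, and the 4 patients E to H had 5′ libraries, with 5039. Median depth per cell was 3933 ± 1116 UMIs at baseline and 4343 ± 991 at 12 weeks (SD, n = 8, exact sign-flip p = 0.0938).

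The level of NKG7 in the blood CD8+ cells did not differ detectably between the time points. Summed over all CD8 cells, NKG7 (ENSG00000105374, a protein-coding gene on chromosome 19 from 51371620 to 51372654 in GRCh38) stood at 3174 ± 1861 CPM, its UMIs scaled to a common library total, at baseline and 2686 ± 1300 at 12 weeks (SD, n = 8). The log2 CPM was higher at 12 weeks in 3 of 8 patients, with a mean difference of −0.17 ± 0.48 (SD, n = 8, exact sign-flip p = 0.367). The edgeR fit gave a log2 fold change of −0.10 (SE 0.13, adjusted p = 1.00), with single patients between −0.85 and 0.40. The mean difference in log2 CPM was −0.30 in the 3′ patients (exact p = 0.50) and −0.03 in the 5′ patients (exact p = 0.875). In the edgeR fit the direction turned in the 5′ patients alone (0.03), with a matched cell make-up (0.04) and without patient C (0.0047).

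The share of CD8 cells with at least 1 NKG7 UMI was 80.7% ± 16.6 at baseline and 76.1% ± 13.8 at 12 weeks (SD, n = 8), a difference of −4.63 percentage points (exact sign-flip p = 0.211). After every cell was thinned to 1000 UMIs the shares were 71.8% ± 18.1 and 65.2% ± 15.4 (SD, n = 8, exact p = 0.172). For comparison, 23.5% of the 277 monocyte-like cells removed from the sort had an NKG7 UMI, at a median of 4268 UMIs per cell, and 15.02% of naive-like CD8 cells had one, at a median of 4737. Thinned, these shares were 9.54% and 4.33%. Of the monocyte-like cells 78 and 93 came from the 2 libraries of patient D, and the source of their NKG7 UMIs was not tested. PDCD1 (ENSG00000188389, chromosome 2 from 241849884 to 241858894), which encodes PD-1, stood at 10.0 ± 7.41 CPM at baseline and 9.70 ± 4.19 CPM at 12 weeks (SD, n = 8), and its log2 difference was 0.02 (exact p = 0.922), with single patients between −0.70 (G) and 0.69 (C). With 10 added to the CPM, these log2 values understate changes at so low a level. Patient C went from 4.58 to 13.5 CPM and patient G from 25.8 to 12.0. The mean log2 difference of PDCD1 was 0.26 in the 3′ patients, C among them, and −0.22 in the 5′ patients, G among them. This difference between chemistries gave an exact permutation p of 0.0857 and was not examined without C or G.

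**Figure D1:**
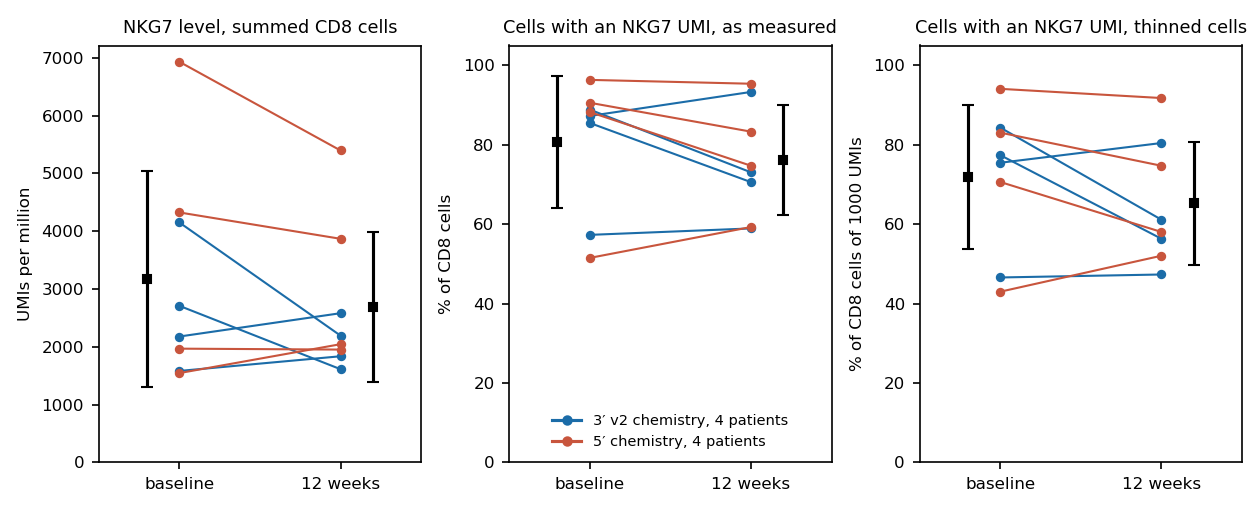
NKG7 in the summed CD8 cells of each library (left, CPM) and the percentage of CD8 cells with an NKG7 UMI, as measured (middle) and in cells thinned to 1000 UMIs (right), at baseline and 12 weeks. Lines join the libraries of a patient, colours give the chemistry and black squares the mean ± SD (n = 8). The level was higher at 12 weeks in 3 of 8 patients.

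Blood CD8+ cells separated into naive-like, memory-like, GZMK memory-like and cytotoxic effector-like cells, with smaller MAIT-like, NK-receptor-high-like and proliferating-like groups. The naive-like cells, led by the lymph node homing receptor CCR7 and the transcription factor LEF1, made up 11.8% ± 13.2 of CD8 cells at baseline and 17.3% ± 12.4 at 12 weeks (SD, n = 8). Their share was larger at 12 weeks in 7 of 8 patients, by 5.46 ± 5.38 percentage points (SD, n = 8, exact sign-flip p = 0.0391), which did not pass adjustment over 8 classes (adjusted p = 0.312). Cytotoxic effector-like cells, led by FGFBP2, the granule protease gene GZMB and GNLY, made up 23.1% ± 26.7 and 18.5% ± 20.6 (SD, n = 8) and were fewer at 12 weeks in 7 of 8 patients (difference −4.66 points, exact p = 0.188). With doublets kept this difference was −5.84 points (exact p = 0.0234, not adjusted), without patient E −6.19 (exact p = 0.0156), without patient C −2.34 (exact p = 0.375) and with unbalanced neighbours −3.29 (exact p = 0.359). None of these passed adjustment, which a single class cannot do with 8 patients or fewer. With 7 patients 0.0156 is the smallest exact p. GZMK memory-like cells made up 24.9% and 26.7% (exact p = 0.523), a difference that was gone without patient A (−0.02 points), and memory-like cells, led by LTB and IL7R, the interleukin 7 receptor, 14.4% and 16.6% (exact p = 0.469).

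A class of 3818 cells stayed unnamed because only 2 fixed markers of any 1 type stood among its 10 leading genes, which included HBA1, GZMH, KLRF1, NKG7 and GNLY. It held 17.2% of CD8 cells at baseline and 13.4% at 12 weeks (exact p = 0.383), a difference of −3.82 points that was −0.85 without patient D. MAIT-like cells, led by SLC4A10 and KLRB1, held 4.43% and 3.39% (exact p = 0.461), NK-receptor-high-like cells, led by TYROBP and KLRC3, 3.04% and 3.52% (exact p = 0.50), and proliferating-like cells, led by STMN1 and TYMS, 1.07% and 0.621% (exact p = 0.961). The last class had a larger share at 12 weeks in 5 of 8 patients, and without patient G its difference turned from −0.446 to 0.426 points. Among the leading genes of the NK-receptor-high-like class was also TRDC, a gene of the gamma delta T list. Whether that class held cells other than CD8+ alpha beta T cells was not tested. No class share passed adjustment (smallest adjusted p = 0.312), whereas 1 class had an unadjusted exact p under 0.05. The difference in the naive-like share was 7.13 points in the 3′ patients (larger in 4 of 4) and 3.79 in the 5′ patients (3 of 4), and the exact p with 4 patients cannot go below 0.125.

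**Figure D2:**
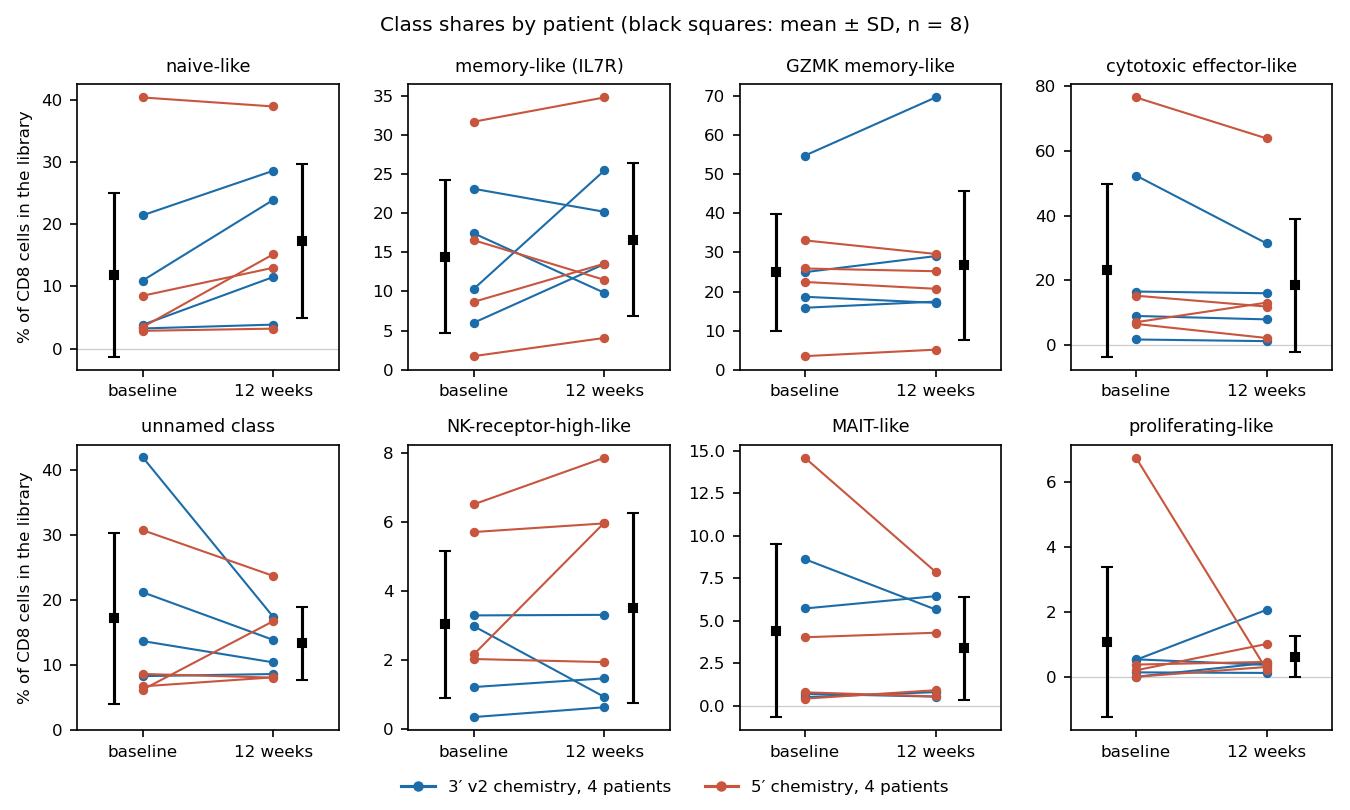
Percentage of a library's CD8 cells in each of 8 classes at baseline and 12 weeks. Lines join the libraries of a patient, colours give the chemistry and black squares the mean ± SD (n = 8). The naive-like share was larger at 12 weeks in 7 of 8 patients.

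Across all CD8 cells, no gene passed the threshold between the time points. SOCS1 (ENSG00000185338, chromosome 16 from 11254417 to 11256204), an inducible inhibitor of cytokine signalling, had the smallest unadjusted p and was higher at 12 weeks in 8 of 8 patients, with a log2 fold change of 1.00 (SE 0.17, adjusted p = 0.633). Next came C1orf162 (0.41), C7orf50 (0.39) and ISG20, an interferon-induced exonuclease gene (0.49), each higher in 8 of 8 patients, and MXD4, which encodes a MAX-binding repressor (−0.43, lower in 8 of 8). MDS2 (0.98), EPHX2 (0.69), ACSM3 (0.67) and MYC, a transcription factor gene of growing cells (0.80), were higher in 7 of 8 patients and FBLN5 (0.71) in 8 of 8. The edgeR test called 0 of 10973 genes, with 515 at an unadjusted p under 0.05, and DESeq2 called 1, SOCS1 (adjusted p = 0.000534), with 300 at an unadjusted p under 0.05. Both of these unadjusted counts lay below what chance alone gives on average. Without the gene filter edgeR called 63 genes, 57 of them higher at 12 weeks, but 60 of the 63 had passed the filter. These calls came mainly from smaller p for the same genes. For SOCS1 the log2 fold change was 1.01 and the unadjusted p 3.26e-17, against 7.16e-05 with the filter. Swaps of the time points within patients gave a median of 50 genes in the same way. The SOCS1 log2 fold change was 1.31 in the 3′ patients and 0.71 in the 5′ patients, and PDCD1 had 0.63 and −0.37.

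Genes of naive and central memory T cells were higher as a group at 12 weeks. Of 20 tested members 19 had a positive log2 fold change, with a median of 0.41, and the list rose by camera (adjusted p = 5.19e-11; adjusted p = 0.245 with an estimated correlation). Its leading members were LRRN3 (1.13), the actin crosslinker gene ACTN1 (0.60), LEF1 (0.51) and CCR7 (0.88). None passed over all genes, and 9 passed when adjusted over the list alone. The mean change of the list was 0.40 ± 0.36 per patient (SD, n = 8, exact p = 0.0234), positive in 7 of 8 patients, with an adjusted p of 0.180 over the lists. The list passed in the 3′ patients (adjusted p = 3.83e-09) and in the 5′ patients (adjusted p = 1.29e-05). The naive-like share, on which some of these genes bear, was larger at 12 weeks by 5.46 points, and with cells matched for class the mean change was 0.11.

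Interferon-response genes were higher by camera as well, mostly in patient E, but not detectably in the test over patients. Of 40 type I interferon response genes 37 had a positive change (median 0.25), and the list rose by camera (adjusted p = 1.41e-05; adjusted p = 0.763 with an estimated correlation), with 1 gene, ISG20 (0.49), passing when adjusted over the list alone. Next in the list were the antiviral genes MX2 (0.53), IFITM3 (0.40) and HERC6 (0.57). Its mean change was 1.79 in patient E and at most 0.176 in the others, the call was lost without patient E (adjusted p = 0.909) and in the 3′ patients (0.171), and it held in the 5′ patients (4.43e-08). Over patients the mean change was 0.24 ± 0.65 (SD, n = 8, exact sign-flip p = 0.414, adjusted p = 0.866 over the lists). Of 31 interferon gamma induced genes 23 had a positive change (median 0.09), and the list rose (adjusted p = 0.0116; adjusted p = 0.763 with an estimated correlation), with 1 gene, SOCS1, passing when adjusted over the list alone, and B2M (0.14) and SOCS3 (0.29) among the next. That call was lost without patient E (adjusted p = 0.547) and in the 3′ patients (0.145). The interferon gamma list had a mean change per patient of 0.13 ± 0.26 (SD, n = 8, exact sign-flip p = 0.219, adjusted p = 0.559 over the lists).

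A further 6 lists rose by camera, all lost with an estimated correlation. Regulatory and CD4 T genes, fixed as a sign of other T cells, had a median of 0.43 with 6 of 7 positive (adjusted p = 0.00969; adjusted p = 0.245 with an estimated correlation), and 2 passed when adjusted over the list alone. TSHZ2 (0.94), IL2RA, an interleukin 2 receptor chain gene (0.78), RTKN2 (0.72) and the inhibitory receptor gene CTLA4 (0.43) led it, and without patient D the adjusted p was 0.0575. The mean change per patient was 0.40 for this list (exact sign-flip p = 0.0234) and 0.33 for monocyte and dendritic genes (exact p = 0.0156). Each was positive in 7 of 8 patients, and both had an adjusted p of 0.180 over the lists, as had the naive and central memory list. Monocyte and dendritic genes, a sign of other cells, had 5 of 5 positive with a median of 0.25 (adjusted p = 0.0255; adjusted p = 0.245 with an estimated correlation), led by AIF1 (0.51) and S100A9 (0.73), and the call was lost in either chemistry alone. Glycolysis genes had 18 of 19 positive with a median of 0.10 (adjusted p = 0.0015; adjusted p = 0.390 with an estimated correlation), led by ALDOC (0.34) and PGK1 (0.22), and the call was lost in the 5′ patients (adjusted p = 0.177). Activation and HLA class II genes had 15 of 19 positive with a median of 0.17 (adjusted p = 0.0255; adjusted p = 0.472 with an estimated correlation), with IL2RA, HLA-DQA1 (0.35) and CD70 (0.27) above 0 and the transferrin receptor gene TFRC (−0.27) below, and the call was lost in the 5′ patients (adjusted p = 0.0713) and without the patient block (0.194). Oxidative phosphorylation genes had 46 of 56 positive with a median of 0.04 (adjusted p = 0.0255; adjusted p = 0.763 with an estimated correlation), led by ATP5MC1 (0.18) and SDHD (0.19), and the call was lost in the 5′ patients (adjusted p = 0.946). Actin cytoskeleton and migration genes had 23 of 28 positive with a median of 0.06 (adjusted p = 0.0448; adjusted p = 0.763 with an estimated correlation), led by CCR7 and VIM (0.22), and the call was lost in either chemistry alone. The calls were also lost without patient A, D or E for monocyte and dendritic genes (adjusted p = 0.0648, 0.117 and 0.0995) and without the patient block (0.114). Without A, D, E or F the activation list had adjusted p = 0.0523, 0.0804, 0.0995 and 0.215, without A, C, D or E the oxidative phosphorylation list 0.170, 0.113, 0.117 and 0.0995, and without A, B, E or F the actin list 0.172, 0.375, 0.138 and 0.137. No member of these last 5 lists passed when adjusted over the list alone. In the exact sign-flip test over patients, p was 0.0469 for glycolysis, 0.0547 for activation, 0.188 for oxidative phosphorylation and 0.180 for actin genes. Adjusted over the lists, these were 0.210, 0.210, 0.539 and 0.539.

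Of the 23 lists tested, 9 passed and 14 did not. Among the latter, 8 of 24 cytotoxic effector genes had a positive change (median −0.04), 13 of 21 lytic granule exocytosis genes (0.02), 10 of 21 NK receptor genes (−0.01), 9 of 16 checkpoint and exhaustion genes (0.04) and 11 of 24 proliferation genes (−0.01). Positive changes were seen for 5 of 11 GZMK effector memory genes (−0.01), 17 of 30 TCR signalling genes (0.01), 16 of 31 immediate early genes (0.02), 12 of 20 heat shock genes (0.10) and 13 of 18 cytokine and chemokine genes (0.08). The remaining lists were mitochondrially encoded genes (10 of 13, median 0.04), MAIT genes (6 of 13, −0.01), gamma delta T genes (1 of 3, −0.21) and B cell genes (2 of 5, −0.08). Their adjusted p lay between 0.0941 (heat shock) and 0.943 (MAIT), and 1 member among them, MYC in the immediate early list, passed when adjusted over the list alone. Under other settings, which were not run with an estimated correlation, some of these lists were called. With cells matched for class 12 lists passed, among them cytotoxic effector (up, adjusted p = 0.000538), checkpoint and exhaustion (up, 0.00801) and lytic granule exocytosis genes (up, 0.0300), whereas cytotoxic effector genes were called down without patient A (0.0334). Proliferation genes were called up without patient G (adjusted p = 9.53e-08) and in the 3′ patients (6.16e-05), and down in the 5′ patients (0.0293). Immediate early genes were called up without C or E (adjusted p = 0.000714 and 0.0130) and heat shock genes up without B or C (0.00183 and 0.0200). For proliferation and B cell genes the test pointed up while the median was negative, with means of −0.09 and 0.10. The test pointed up for MAIT genes with a median of −0.01, and down for GZMK effector memory and NK receptor genes with means of 0.01 and 0.0012. Platelet, erythroid and nuclear RNA lists had too few measured genes to test, and CLU (0.33), SLC25A37 (−0.02), NEAT1 (−0.11) and MALAT1 (−0.01) did not pass.

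**Figure D3:**
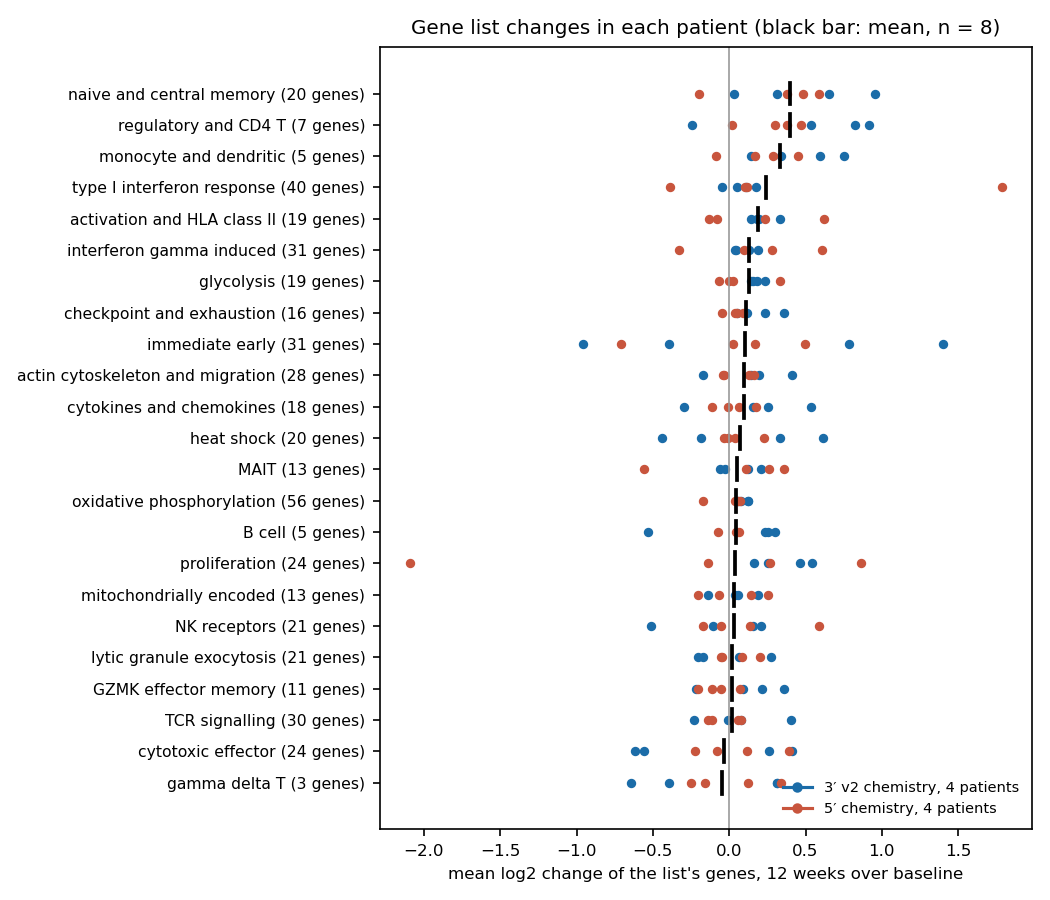
Mean log2 change of each gene list from baseline to 12 weeks in each patient (points, coloured by chemistry) with the mean over patients (black bar, n = 8). The naive and central memory list had a mean of 0.40, and patient E stands apart in the type I interferon list at 1.79.

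Within single classes of CD8 cells no gene passed the threshold either, and NKG7 did not differ detectably, with log2 fold changes between −0.10 and 0.05 over 6 classes and unadjusted p between 0.473 and 0.740. Among memory-like cells the survival kinase gene PIM1 (0.60), SOCS1 (0.68) and PARP9 (0.87) were higher at 12 weeks in 7 of 8 patients, and SSBP3 (−0.83), GXYLT1 (−0.92), MAPK6 (−0.89), RAB11FIP1 (−0.64), AAED1 (−0.86) and RAB1A (−0.63) were lower. Among GZMK memory-like cells PLP2 (0.45), HLA-DQA1 (0.50), SOCS1 (0.97), ISG20 (0.49) and SDR42E2 (0.70) were higher, and AXIN1 (−0.76), PPP1R12C (−0.70), NPLOC4 (−0.60), YARS2 (−0.63) and CSNK1G2 (−0.53) lower. Naive-like cells had higher LGALS3BP (0.92), MYC (0.57), IFI35 (0.83), C7orf50 (0.64), ACTG1 (0.28), MRPL1 (0.63), ACTB (0.22) and TRIM22 (0.55) and lower COQ10B (−0.71). In cytotoxic effector-like cells LINC02256 (0.94), CEBPB (0.62), KIAA2013 (0.65), EXOSC5 (0.71) and GPR65 (0.46) were higher and TCP11L2 (−0.96), EZH2 (−0.84), Z93241.1 (−0.87), ATXN1 (−0.51) and FAM53C (−0.76) lower. NK-receptor-high-like cells had lower ZNF683 (−0.89), CSKMT (−1.04), KMT2E-AS1 (−0.76), CD96 (−0.60), MED28 (−0.87) and MRPL10 (−0.65) and higher MT-ATP8 (0.42), GPAA1 (0.79) and TXNIP (0.40). In the unnamed class CEBPB (0.66), C7orf50 (0.54), B2M (0.19), ZFP36L2 (0.48), JUNB (0.46), SRGN (0.31), HERPUD1 (0.56) and CCL4 (0.51) were higher and UBR1 (−0.77) and SLF1 (−0.55) lower. These genes did not pass. The edgeR test called 0 genes in each of the 6 classes, with 1256 of 35089 gene tests at an unadjusted p under 0.05, and DESeq2 called 0 in each.

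Type I interferon response genes rose by camera in all 6 tested classes, with adjusted p over all classes and lists between 1.63e-06 and 0.0428, and interferon gamma induced genes rose in 5. With an estimated correlation the smallest unadjusted p was 0.122 for the type I interferon list and 0.0567 for the interferon gamma list. Without patient E the type I interferon list passed in 0 of 6 classes (smallest adjusted p = 0.147). Cytotoxic effector genes rose by camera in 4 classes (smallest unadjusted p = 0.0587 with an estimated correlation), whereas immediate early genes fell in naive-like cells (adjusted p = 0.0117; unadjusted p = 0.336 with an estimated correlation). In all, 22 pairs of list and class passed by camera, and 0 with an estimated correlation.

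NKG7 differed by orders of magnitude between classes of CD8 cells at baseline. Naive-like cells had 56.3 ± 32.0 CPM (SD, n = 7), memory-like cells 352 ± 170 (SD, n = 8), MAIT-like cells, which entered no test, 1591 ± 599 (SD, n = 4) and GZMK memory-like cells 2933 ± 715 (SD, n = 8). The unnamed class had 4845 ± 1084 CPM (SD, n = 8), NK-receptor-high-like cells 5742 ± 1173 (SD, n = 6) and cytotoxic effector-like cells 5767 ± 1220 (SD, n = 7). The clustering did not use NKG7. Between neighbouring classes the level was higher by 2.45 on the log2 scale in memory-like than in naive-like cells (7 of 7 patients, adjusted exact p = 0.0260), by 3.17 in GZMK memory-like than in memory-like cells (8 of 8, adjusted exact p = 0.0195) and by 0.73 in the unnamed class than in GZMK memory-like cells (8 of 8, adjusted exact p = 0.0195). The unnamed class and the NK-receptor-high-like class differed by 0.16 (5 of 6, adjusted exact p = 0.0781) and the NK-receptor-high-like and cytotoxic effector-like classes by 0.05 (4 of 6, adjusted exact p = 0.344). After thinning to 1000 UMIs, 6.73% of naive-like, 22.5% of memory-like, 85.5% of GZMK memory-like, 97.4% of NK-receptor-high-like, 97.5% of cytotoxic effector-like and 98.0% of unnamed cells had an NKG7 UMI, and 2 of 5 neighbouring pairs passed in this order. With 4 or fewer patients in a chemistry the exact test cannot pass; the first 3 differences were 1.96, 3.397 and 0.76 in the 3′ patients and 2.82, 2.94 and 0.69 in the 5′ patients.

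**Figure D4:**
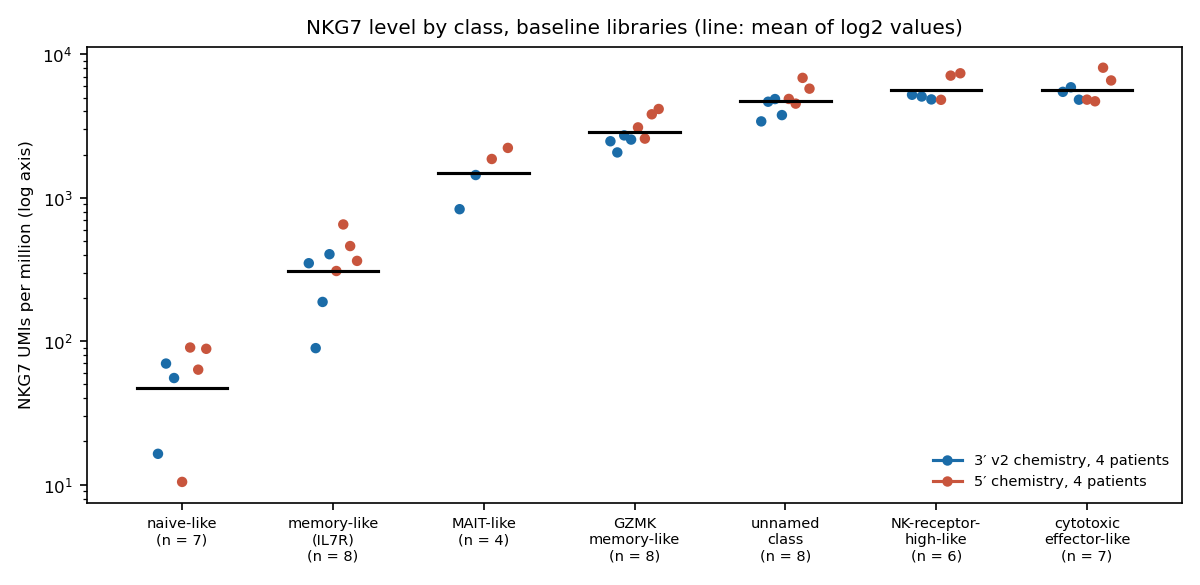
NKG7 level (CPM, log axis) in each class of CD8 cells at baseline. Points are patients with at least 20 cells of the class, coloured by chemistry, and lines the mean of the log2 values, from 5.84 in naive-like to 12.47 in cytotoxic effector-like cells.

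Cytotoxic genes were higher in CD8 cells with an NKG7 UMI and naive genes in cells without one. Granule and killing genes were higher in cells with NKG7, among them the protease genes GZMB (log2 fold change 4.52, SE 0.27, adjusted p = 1.75e-09) and GZMH (3.79) and the lytic peptide gene GNLY (2.77). FGFBP2 (4.23), the adhesion receptor gene ADGRG1 (3.899), the Fc receptor gene FCGR3A (3.85), the egress receptor gene S1PR5 (3.63), TTC38 (3.07), the chemokine gene CCL4 (2.98), C1orf21 (2.97), the interferon gamma gene IFNG (2.95) and FGR (2.93) were higher too. Lower were MAL (−5.58), CCR7 (−4.76, SE 0.25, adjusted p = 5.32e-13), SPINT2 (−3.67), RCAN3 (−3.53), NELL2 (−3.18), ARMH1 (−3.14), LEF1 (−3.12), SERINC5 (−2.86), TXK (−2.74), TRABD2A (−2.50), MYC (−2.42) and LTB (−2.35). The edgeR test called 1122 of 4554 genes, 536 higher and 586 lower in cells with NKG7, and cells on both sides were thinned to 1000 UMIs.

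Among the lists, 19 of 20 cytotoxic effector genes, 7 of 8 NK receptor genes, 11 of 18 lytic granule exocytosis genes, 6 of 8 checkpoint and exhaustion genes, 8 of 9 activation and HLA class II genes, 15 of 26 interferon gamma induced genes, 12 of 29 TCR signalling genes and 12 of 26 actin cytoskeleton and migration genes were higher in cells with NKG7. Lower were 15 of 17 naive and central memory genes, 12 of 24 immediate early genes and 9 of 13 mitochondrially encoded genes. Within memory-like cells alone, a comparison chosen after the data were seen, 17 genes passed in 6 patients, among them, named after their values were seen, GZMA (1.95), LYAR (1.15), GZMK (1.14) and CCL5 (1.09) higher and RPS18 (−0.25) and EEF1G (−0.70) lower. There 3 of 7 cytotoxic effector genes were higher, but 0 of 8 naive and central memory, 0 of 16 immediate early and 0 of 13 mitochondrially encoded genes were lower. Within GZMK memory-like cells alone 23 genes passed in 7 patients. Post-treatment libraries gave 1822 genes, of which 954 were also called at baseline, all 954 in the same direction. Without thinning 2865 genes passed.

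**Figure D5:**
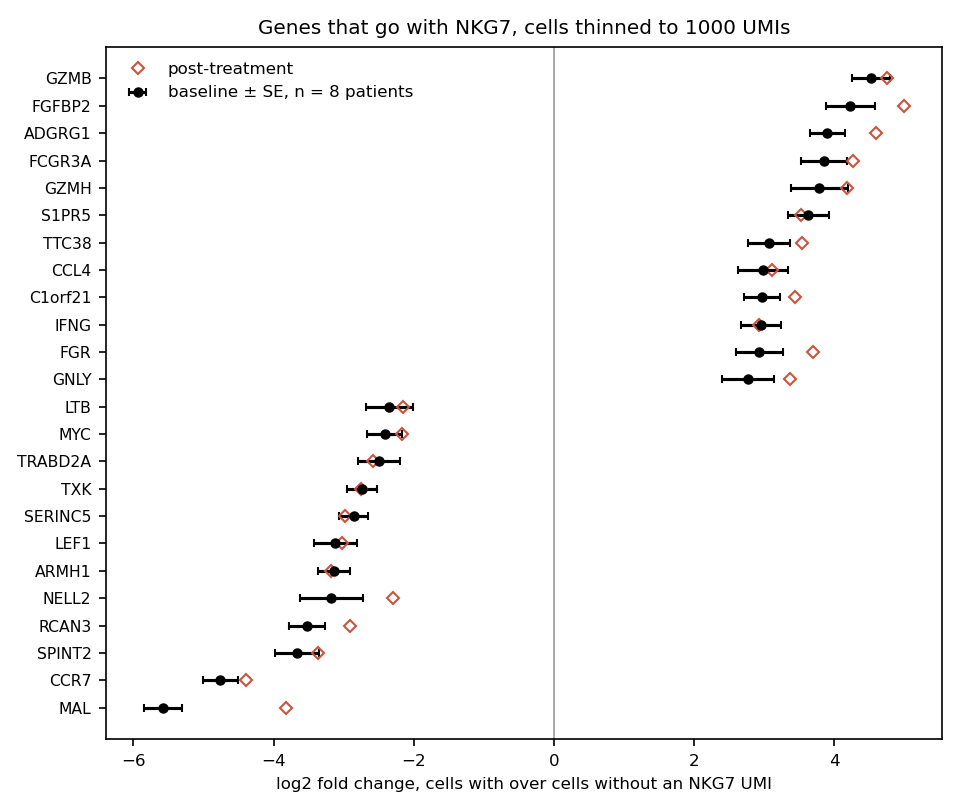
Log2 fold change between cells with and without an NKG7 UMI (thinned to 1000 UMIs) for the 24 named genes, at baseline (points ± SE, n = 8 patients) and post-treatment (open diamonds). GZMB stands at 4.52 and CCR7 at −4.76 at baseline.

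The change with treatment did not differ detectably between the chemistries for any gene. The edgeR interaction called 0 genes, with 180 at an unadjusted p under 0.05, and DESeq2 called 0, with 62. Both unadjusted counts lay below what chance alone gives on average. The smallest unadjusted p belonged to the cell-cycle inhibitor gene CDKN2D (0.84, 5′ minus 3′ patients), S100A9 (−1.86), CES1 (0.90), CCDC22 (−0.68), PDXK (−0.86), GPR171 (−0.92), ATG9B (−1.37), AC097376.2 (−0.70), CARS (−0.59) and PLPP1 (−1.62), which did not pass. By camera 4 lists differed, with a mean change that was larger by 0.176 in the 5′ patients for cytotoxic effector and by 0.332 for type I interferon genes, and by −0.628 for proliferation and −0.0965 for oxidative phosphorylation genes. With an estimated correlation the unadjusted p were 0.452, 0.370, 0.195 and 0.248 in that order, and an exact permutation of patients gave p = 0.571, 0.743, 0.543 and 0.0571. Leaving out single patients, a comparison chosen after the data were seen, turned the type I interferon difference to −0.13 without patient E, left −0.02 for proliferation without patient G and gave 0.01 to 0.35 for cytotoxic effector genes.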

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

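Chosen only after the result was seen were the tests of cell make-up for naive genes, of red cells and free red cell RNA for haemoglobin, and of chance for the all-cell genes, the genes within classes and the interaction with chemistry. Of 67 groups of values examined for a sample far from the rest, 11 had one, where chance alone gives about 1 in 20 groups, or 3.4.

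Naive and central memory genes were higher at 12 weeks, with a mean change of 0.40 ± 0.36 over 8 patients (SD). The mean was 0.41 with all barcodes kept and 0.34 with every cell thinned to 1000 UMIs. This argues against the cell filter and against the larger weight of deep cells in the sums as its cause. Thinning keeps each cell's expected proportions, so it cannot decide on other effects of depth. With the classes matched between a patient's libraries it was 0.11 ± 0.0998 (exact p = 0.0313). But 7 of the 10 leading genes of the naive-like class belong to the list, so that more naive-like cells and higher naive genes within cells cannot be told apart. Why either came about, treatment included, was not tested. Chance stays open for the rise itself. The exact sign-flip test gave an adjusted p of 0.180 over the lists, and camera with an estimated correlation 0.245. Swapping the time points within patients was not tried for this list alone.

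SOCS1 was higher at 12 weeks in 8 of 8 patients, with a mean of 1.02 ± 0.59 (SD). Matched classes gave 0.91, all barcodes 1.08 and thinned cells 0.94. This argues against cell make-up, the cell filter and the larger weight of deep cells as its whole cause, while other effects of depth stay open. Chance could not be excluded: 20 of 100 swaps of the time points within patients, the real one included, had a smallest p over all genes of 7.16e-05 or lower, and the lowest was 9.46e-08. An effect of treatment stays a hypothesis beside chance.

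Haemoglobin genes HBA1 and HBA2 led the unnamed class, in a sort for CD45, CD3 and CD8. A planned comparison of HBA UMIs per cell with the other classes (a ratio of 3.42, in only 4 libraries with at least 20 such UMIs, from 2 patients) restates the pattern and decides nothing. Red cells, or free RNA from them, would bring HBB, which came to 0.0554 UMIs per 100 of HBA1 and HBA2 in patient B (1 against 1804), which argues against both there, but to 3.93 in patient D (7 against 178), where both stay open. These UMIs were counted over all CD8 cells of the patient's libraries, and HBB was not counted for the unnamed class alone. Doublets would carry more UMIs, and the class had 0.86 of its library's median. No biological explanation was tested, and reads shared between near-identical genes stay open.

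Other values stood apart from the remaining patients of their group. The GZMK memory-like share at 12 weeks was 69.6% in patient A, with the next at 29.6%. The change in that share was 14.9 points in patient A, with the next at 4.10. The proliferating-like share at baseline was 6.76% in patient G (109 of 1613 cells, exact 95% interval 5.58 to 8.09), with the next at 0.539%. At 12 weeks it was 2.07% in patient C, with the next at 1.01%, and its change was −6.54 points in patient G, with the next at −0.172. PDCD1 stood at 25.8 CPM at baseline in patient G, with the next at 12.4. The proliferation list changed by −2.09 in patient G, the type I interferon list by 1.79 in patient E, the oxidative phosphorylation list by −0.168 in patient G, the MAIT list by −0.556 in patient F and the B cell list by −0.532 in patient A.

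The change of 4 lists differed between chemistries by camera. The 5′ minus 3′ difference was 0.176 for cytotoxic effector genes (adjusted p = 0.0392), −0.628 for proliferation (1.42e-05), 0.332 for type I interferon response (0.00024) and −0.0965 for oxidative phosphorylation (0.00715). With an estimated correlation the unadjusted p were 0.452, 0.195, 0.370 and 0.248. The proliferation difference was −0.02 without patient G and the interferon difference −0.13 without patient E, values chosen after the result was seen.

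For the counts of genes, swapping the time points within patients asked whether chance can be excluded. A count of 0 is matched by every swap and so tests nothing: this holds for all CD8 cells (100 of 100, highest other 130), for the genes within classes (40 of 40, highest other 471) and for the interaction (35 of 35 splits of patients, highest other 169). At an unadjusted p under 0.05 the real count was 515, 36 of 100 swaps gave as many and the highest other was 2075. Without the gene filter 19 of 40 swaps gave 63 genes or more (highest other 813). All 39 other swaps called genes this way, with a median of 50. With DESeq2 12 of 40 gave 1 or more (highest other 327). The 9 lists were matched in 24 of 100 swaps (highest other 15), and the swaps gave a median of 6 lists, with 1 as the lowest. Chance was not excluded for these 4 counts above 0, and swaps with far more genes than the real time points point to structure among the samples. For genes that go with NKG7 chance was excluded: 1 of 100 swaps, the real one, gave 1122 genes and the highest other 679.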

How the results depend on the processing

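The comparisons of NKG7 within memory-like and within GZMK memory-like cells, all alternatives for gene lists within classes and the list differences between chemistries without single patients were chosen only after the result was seen. Planned restriction of the NKG7 comparison to cytotoxic effector-like cells gave no value, since 0 patients had 20 cells on both sides. The cause of the changes below was not tested unless stated.

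For all CD8 cells edgeR called 0 genes under 18 of 20 alternatives, DESeq2 called 1 and edgeR without the gene filter 63. Leaving out any patient gave 0 genes each time, also for the interaction with chemistry. The NKG7 log2 fold change was −0.10, and −0.16 with no replicate block. It lay between −0.17 and 0.0047 when patients were left out, the latter without patient C, and was −0.23 in the 3′ patients, 0.0288 in the 5′ patients and 0.0438 with matched classes, all short of the threshold. No class share passed under any of the 16 alternatives; the naive-like share, unadjusted, had p = 0.401 by permutation without pairing and an exact p of 0.0781 without B, C, D, F or H. The cytotoxic effector-like share, unadjusted, had an exact p of 0.188, which lay between 0.0156 (without E) and 0.50 (5′ patients) under the alternatives, and p = 0.734 by permutation without pairing.

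The 9 lists became 0 with an estimated correlation, 0 by fry, 5 in the 5′ patients and 12 with matched classes. Leaving out patients gave 4 (without E) to 10 lists, with 5 without D, and no replicate block gave 7. Direction reversed for cytotoxic effector genes with matched classes (up, adjusted p = 0.000538) and for proliferation genes in the 5′ patients (down, adjusted p = 0.0293). The type I interferon difference between chemistries lay between −0.129 (without E) and 0.598 (without G), and 31 of 32 such differences over 4 lists kept their sign. Over the single lists, 229 of 322 results kept direction and call, 47 lost the call and 9 gained it. The 22 pairs of list and class became 0 with an estimated correlation and 8 (without B) to 25 when patients were left out, with 12 without E.

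Within classes 0 genes became 0 to 3 when patients were left out: 3 without D, and 1 each without E, G and H. These genes, named after their values were seen, were PIM1 in memory-like and EGR1 and HIST1H2BC in naive-like cells, and JUNB, ACTG1 and CCL4 in the unnamed class.

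The 1122 genes that go with NKG7 became 382 with no replicate block, 1822 post-treatment, 2865 without thinning, 17 in memory-like and 23 in GZMK memory-like cells alone. In the latter the folds were smaller too, as for GZMH (3.79 to 1.66), CCL4 (2.98 to 0.64) and LTB (−2.35 to −0.90). Leaving out patients gave 895 to 1189, and DESeq2 795. The alternative with no replicate block was not run for the interaction with chemistry or for lists within classes. Of 5 neighbouring class pairs 3 differed in NKG7, 4 post-treatment, 2 for the thinned share of cells with a UMI, where the unnamed class came highest, and 0 in the 3′ or 0 in the 5′ patients alone, where the exact test cannot pass with 4 patients. Small changes can be missed: simulated 1.5-fold changes were recovered for 26% of genes across cells and 6% in the interaction. The shares were 86% for all CD8 cells and 70% within the memory-like class, all for genes above the median level.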

Other observations

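PDCD1, the gene of the antibody's target, was seen in few cells of every class. As measured over all libraries, 13.7% of proliferating-like cells had a PDCD1 UMI, at a median depth of 9371 UMIs per cell, but 112 of these 205 cells came from patient G, whose PDCD1 level at baseline stood apart from the others. The share was 6.53% of GZMK memory-like cells (median depth 3696), 5.18% of NK-receptor-high-like cells (4325), 4.87% of cytotoxic effector-like cells (3667) and 4.70% of MAIT-like cells (4273). It was 2.36% of the unnamed class (3182), 2.09% of memory-like cells (4761) and 0.236% of naive-like cells (4737), so that the naive-like class had the lowest share at a depth above that of the GZMK memory-like class. Patient G gave 2127 of the 5006 cytotoxic effector-like but 128 of the 5542 GZMK memory-like cells, and the order of these shares was not examined within patients. These shares pool cells over patients, were not thinned and carry no test. Of 277 monocyte-like cells 0 had a PDCD1 UMI, where 3 would have been 1.08%. The checkpoint and exhaustion list had a median log2 fold change of 0.04 at 12 weeks with 9 of 16 genes positive. Its mean change per patient was 0.11 ± 0.13 (SD, n = 8), positive in 7 of 8 patients (exact sign-flip p = 0.0313, adjusted p = 0.180 over the lists). Its leading members by p, HAVCR2 (0.54), TIGIT (0.29), CTLA4 (0.43) and PRDM1 (0.25), did not pass.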
